A study of Homo sapiens with 24 samples.

How the data were processed

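Gene expression was measured in cultured punches of human fetal membranes on Affymetrix arrays, 1 array per sample, from biotin-labelled cRNA per the labels' protocols. The 24 arrays form 6 groups of 4: membranes given GBS or vehicle control and taken at 4, 8 or 24 h. The labels number the arrays of each group 1 to 4, and the series' design text says that membranes of 4 donors were used for each condition and time. The labels give the abbreviation GBS only, which is read here as group B Streptococcus from what is known of the study. Strain, dose and the time from delivery to culture are not given in the sources used here.

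The values are log2 expression values per probeset as the authors deposited them. Per the submitters' processing notes they were made with RMA and R 3.1.2. RMA corrects the background, normalizes by quantiles and summarises the probes of a probeset. The package, the probe annotation and any filter are not given in the sources used here, nor is a genome build, so no coordinates are printed. The table holds 53617 probesets with values from -0.30 to 13.52. RMA values carry no depth or detection call, and the number of arrays limits the precision. Over all probesets the arrays' medians lay between 1.46 and 1.64 and their 75th percentiles between 3.43 and 3.69. Correlations between pairs of arrays ran from 0.941 to 0.979, so no array was a copy of another.

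Probesets were named through the platform annotation. In it 23871 probesets have 1 gene symbol, 1842 have several and 27904 have none, and only those with 1 symbol were named. Symbols were updated to those of the RefSeq annotation of GRCh38.p14, 22569 probesets by gene ID, 733 by symbol and 565 by a synonym, while 4 kept the older name. XIST and Y-linked genes (46 probesets) were removed from every table. Of the 22312 genes left, 662 had more than 1 probeset, and the probeset with the highest mean over all arrays stood for the gene. Genes with a mean under 1.07 log2, the 25th percentile of all probeset means, were not tested, which left 19348 genes. Genes missing from a list below had no probeset with a single symbol or lay under that floor and were not analysed here.

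Differences were tested with lmFit and eBayes of limma 3.58.1 in R 4.3.3, in 1 fit of all 24 arrays with 6 group means and 18 residual degrees of freedom. P-values are two-sided and Benjamini-Hochberg adjusted over the genes tested, with a threshold of 0.05. The contrasts were GBS minus control at each time, their mean over the 3 times, the difference of the GBS effect at 8 or 24 h from that at 4 h, and controls at 8 or 24 h minus controls at 4 h. Whether the replicate numbers pair the arrays was checked on the deviations of each array from its group mean. All 60 pairs of arrays with the same number in 2 groups correlated above 0.1 (lowest 0.138, median 0.319), against a median of -0.112 and a highest value of 0.224 over the 180 pairs with different numbers. The numbers were therefore taken to pair the samples, on the basis of the data and not of a label. A fit with the number as a block has 15 residual degrees of freedom. Standard errors and adjusted p-values of single genes, and counts of list members past the test, come from that blocked fit. The log2 fold changes are the same in both fits. Counts of all genes are given from the fit without the block, with the blocked count beside them.

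Before the data were examined, 21 gene lists and 12 lists of cell type markers were fixed, as was the rule for the genes named. At each time these are the 12 rising and 8 falling genes with the largest change among those past the blocked test and changed in the same direction in 4 of 4 pairs. Added to them are, per list, up to 4 such members, or up to 2 members with the largest change where none passed, and 5 genes per direction for the contrasts between times. A gene named outside that rule is said to be so. The lists were tested with camera, with a preset inter-gene correlation of 0.01 and with the correlation estimated, and with fry, adjusted over the 33 lists within a time. Member counts are also given adjusted over the list alone.

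The fits were tested on simulated data made from the real genes' means, replicate number effects and residual spreads. At 24 h, among 19348 genes, changes of 1 log2 unit were recovered in 44.8% of cases without the block and 70.1% with it, and changes of 2 log2 units in 89.4% and 97.0%. Camera found 40 of 40 lists shifted by 1 log2 unit in 20 draws at 8 h. The residuals of the simulated genes were drawn independently, so this does not test camera on lists whose members correlate. Alternatives covered the block, the samples in the fit, the variance model, array weights, a second quantile normalization, centring of the arrays, the filter, the choice of probeset, the adjustment, a fold threshold and leaving out each array or replicate number. Removal of a trend with gene span, together with each array's overall level, was added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.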

Results

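Expression was profiled on 24 arrays in punches of human fetal membranes, the sac of amnion and chorion that surrounds the fetus, kept in culture. The punches received GBS (group B Streptococcus, a bacterium that can infect these membranes) or vehicle, and 4 arrays were made for each treatment at 4, 8 and 24 h. Changes below are log2 differences of RMA values, GBS minus control, as mean ± standard error with n = 4 per group. The standard error rests on a spread that the fit estimates over all 24 arrays. It does not describe the spread within the groups compared, which the SDs give. Group levels are log2 values as mean ± SD. Named changes had the same sign in 4 of 4 pairs of arrays with the same replicate number, unless stated otherwise.

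The comparison at 4 h asked which transcripts differed soon after GBS was added. Inflammatory cytokine and chemokine genes and regulators of NF-κB rose. TNF, a cytokine that starts inflammatory signalling, rose by 4.56 ± 0.35 (23.6-fold), from 3.97 ± 0.49 in controls to 8.53 ± 0.27. SELE, the adhesion molecule E-selectin of activated endothelium, rose by 4.38 ± 0.47 (20.9-fold). The chemokine genes CCL4, CCL20 and CXCL2 rose by 3.30 ± 0.35, 2.98 ± 0.26 and 2.23 ± 0.32. IL6 rose by 2.54 ± 0.24 and IL1B by 2.03 ± 0.20. PTX3, a secreted pattern recognition protein, rose by 2.52 ± 0.32. TNFAIP3 and NFKBIA, feedback inhibitors of NF-κB, rose by 2.32 ± 0.19 and 2.08 ± 0.22. EGR1, an immediate early transcription factor, rose by 2.22 ± 0.25, and G0S2, an inhibitor of lipolysis, by 2.07 ± 0.25. Adjusted p-values of these 12 genes ran up to 0.00096, and without the replicate block G0S2 missed the threshold (adjusted p = 0.055). FAM182A fell with the block (adjusted p = 0.0092, and 0.079 without it), from 2.09 ± 0.62 in controls to 0.97 ± 0.18, a level under the expression floor, so the size of its change is not given.

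Among the lists fixed beforehand, 5 of 16 cytokine genes rose at 4 h (7 adjusted over the list alone), as did 5 of 21 chemokine genes (8 over the list alone). Of the NF-κB targets and regulators 6 of 16 rose (14 over the list alone). Of the immediate early genes 4 of 17 rose (10 over the list alone, and 3 after centring or a second quantile normalization). These 4 lists passed camera with an estimated correlation (adjusted p = 1.67e-05, 0.000421, 3.39e-06 and 4.58e-05). IL1A rose by 2.02 ± 0.30, CXCL8 by 1.58 ± 0.25, NFKBIZ by 1.95 ± 0.23, JUNB by 1.40 ± 0.20 and IER3 by 1.62 ± 0.25, CXCL8 and IER3 only with the block. TLR2, a receptor for bacterial lipoproteins, rose by 1.12 ± 0.19 with the block (adjusted p = 0.0089, and 0.38 without it), and PTGER4, a prostaglandin E2 receptor, by 1.93 ± 0.24. TLR2 and PTGER4 were the single members past the test in lists of 19 pattern recognition and 16 prostaglandin genes, and no member of the other lists passed. Of 22 matrix proteases and inhibitors 0 passed (2 adjusted over the list alone), with a difference of 0.75 ± 0.16 for PLAU (adjusted p = 0.065). That list passed camera with an estimated correlation with the block (adjusted p = 0.0155) and not without it (adjusted p = 0.416). In all, 20 of 19348 genes rose and 0 fell, and with the replicate block 35 rose and 1 fell. Without replicate number 4 the blocked count of 36 was 22.

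The comparison at 8 h asked the same question later. Cytokine, chemokine and NF-κB genes rose, and a marker of decidual stroma and a macrophage gene were among those that fell. SELE rose by 6.48 ± 0.47 (89.2-fold), from 1.70 ± 0.27 to 8.18 ± 0.89. CCL20 rose by 4.99 ± 0.26, TNF by 4.84 ± 0.35 and IL6 by 4.28 ± 0.24. IL23A, a subunit of interleukin 23, rose by 4.19 ± 0.81 with the block (adjusted p = 0.0065, and 0.069 without it). PTGS2, the inducible enzyme of prostaglandin synthesis, rose by 3.78 ± 0.33 and EREG, a growth factor of the EGF family, by 3.57 ± 0.52. PTX3, G0S2, CCL4 and CXCL2 rose by 3.21 to 3.60. TNIP3 rose from 1.16 ± 0.05, close to the expression floor, to 4.44 ± 1.21. DKK1, a secreted Wnt antagonist and a marker of decidual stroma, fell by 2.28 ± 0.29, from 9.81 ± 0.33 to 7.53 ± 1.18. The macrophage gene MPEG1, which codes for a pore-forming protein, fell by 2.18 ± 0.52 with the block (adjusted p = 0.035, 0.2 without it and 0.053 after a second quantile normalization). FGL2 fell by 1.99 ± 0.36, GPR34 by 1.98 ± 0.34, RNASE6 by 1.90 ± 0.39, RAB42 by 2.17 ± 0.28, ADAP2 by 2.14 ± 0.25 and the scavenger receptor gene COLEC12 by 1.77 ± 0.22. FGL2 and RNASE6 passed only with the block, and GPR34 lay close to the floor with GBS (1.42 ± 0.25).

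Of the 16 NF-κB targets and regulators 15 rose at 8 h (16 adjusted over the list alone), of the 21 chemokines 11 (13) and of the 16 cytokines 9 (12). Of the 17 immediate early genes 6 rose (9 over the list alone). LIF rose by 3.15 ± 0.23, CXCL3 by 3.19 ± 0.48, TRAF1 by 2.67 ± 0.27 and IER3 by 2.13 ± 0.25. These 4 lists passed with an estimated correlation (largest adjusted p = 0.00137, for the immediate early genes). Of 22 matrix proteases and inhibitors 6 rose (over the list alone 6 rose and 2 fell). MMP1, the interstitial collagenase, rose by 2.47 ± 0.40, MMP3 by 2.01 ± 0.38, the urokinase gene PLAU by 1.55 ± 0.16 and ADAMTS4 by 1.20 ± 0.27, and of these 4 only PLAU passed without the block. That list's adjusted p with an estimated correlation was 0.0057 with the block and 0.136 without it. Of 14 cell death regulators FAS, a death receptor gene, rose by 1.70 ± 0.28 (3 members over the list alone, 2 after centring or a second quantile normalization, adjusted p = 0.0129 with an estimated correlation).

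Other lists had from 0 to 5 members past the test at 8 h. TLR2 rose by 2.35 ± 0.19 and the inflammasome gene NLRP3 by 1.80 ± 0.42, while TLR6 fell from 1.89 ± 0.49 to 0.90 ± 0.16, a level under the expression floor, and NLRP3 passed only with the block. Of that list's 19 members 4 rose and 1 fell (over the list alone 5 and 3, adjusted p = 0.768 with an estimated correlation). CLDN1, a tight junction claudin, rose by 1.74 ± 0.28. With the block LAMB3, a basement membrane laminin chain, rose by 1.17 ± 0.15 and the epithelial gene SFN by 1.12 ± 0.24, and neither passed without it. GBP1 rose by 1.82 ± 0.32 with the block (adjusted p = 0.0027, and 0.45 without it) and was the only 1 of 23 interferon-stimulated genes past the test. The macrophage markers had a median of -0.65 over 10 members, of which MS4A7 fell by 1.08 ± 0.24, and it missed the threshold after a second quantile normalization (adjusted p = 0.079). With the preset correlation that list and those of decidual stroma, proliferation (all lower) and hypoxia (higher) also passed camera, and with the block the epithelial markers too. None of them held with an estimated correlation and the block (adjusted p = 0.15, 0.206, 0.417, 0.199 and 0.199). In all, 94 genes rose and 17 fell at 8 h, and with the replicate block 222 rose and 133 fell. The arrays' medians over the tested genes were lower by 0.117 log2 in the GBS group at 8 h, and after centring them 334 rose and 75 fell with the block. Without replicate number 1, 2 or 4 the unblocked count was 54, 54 and 64 genes and the blocked count of 355 was 127, 173 and 156.

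**Figure D1:**
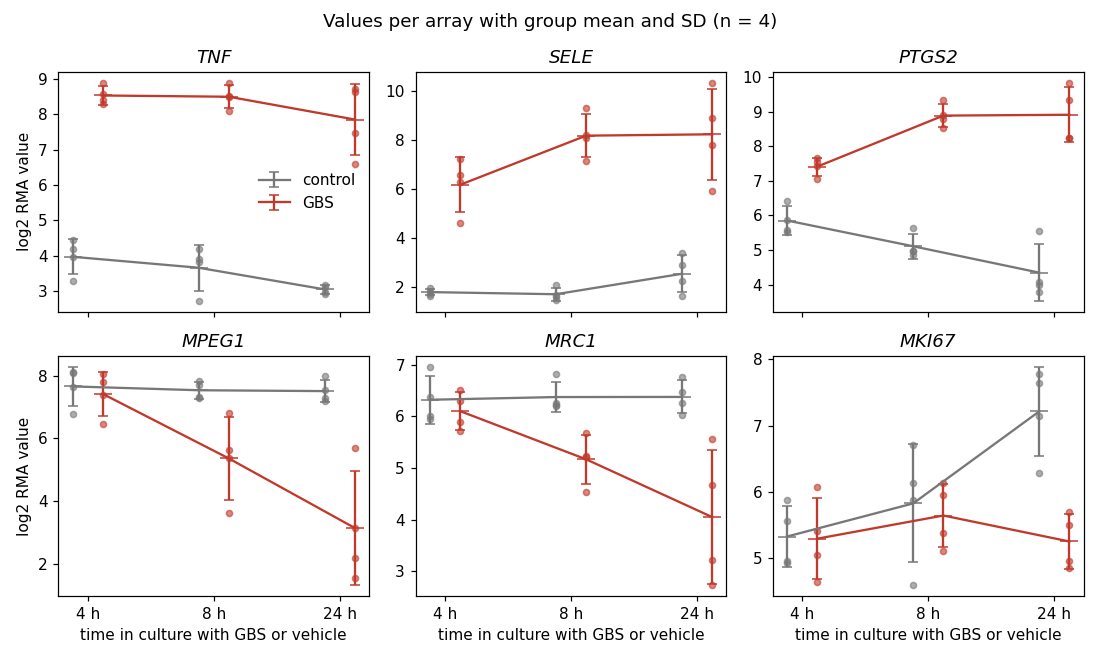
Values of 6 genes on the log2 RMA scale (vertical axis) at 4, 8 and 24 h (horizontal axis, equally spaced and not to scale in time) in control (grey) and GBS-treated (red) membranes. Points are arrays, and the lines join group means with SD bars (n = 4). TNF, SELE and PTGS2 lie higher with GBS, MPEG1 and MRC1 fall in the GBS groups, and MKI67 in controls goes from 5.32 at 4 h to 7.21 at 24 h.

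At 24 h cytokine, chemokine and NF-κB genes were raised, and some macrophage and cell cycle genes fell. SELE rose by 5.70 ± 0.47 (51.9-fold), TNF by 4.81 ± 0.35, IL23A by 4.65 ± 0.81 and CSF3, the granulocyte colony-stimulating factor gene, by 4.59 ± 0.61. PTGS2 rose by 4.57 ± 0.33, from 4.35 ± 0.82 to 8.92 ± 0.80. CCL20, IL6, CXCL2, TNFAIP6, ICAM1, PTX3 and IL6-AS1 rose by 3.43 to 4.20. ICAM1 codes for a leukocyte adhesion molecule and TNFAIP6 for a hyaluronan-binding protein. MPEG1 fell by 4.37 ± 0.52, from 7.51 ± 0.36 to 3.14 ± 1.82. FGL2 fell by 3.13 ± 0.36 and FPR3, a formyl peptide receptor gene, by 3.02 ± 0.39. The small RNA genes SNORD114-17, SNAR-E and MIR181B2 fell by 3.61 ± 0.64, 2.81 ± 0.57 and 2.64 ± 0.39. ZNF493 fell by 2.65 ± 0.40, to 1.29 ± 0.47 and so close to the floor, and the antisense gene ZNF276-AS1 by 2.66 ± 0.37. Adjusted p-values of these 20 genes were at most 0.0025 with the block and 0.026 without it.

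All 16 NF-κB targets and regulators rose at 24 h (16 over the list alone), with ICAM1 (3.59 ± 0.25) and TNFAIP3 (3.07 ± 0.19) the largest. Of 21 chemokines 13 rose (over the list alone 14 rose and 1 fell), of 16 cytokines 10 (11) and of 17 immediate early genes 12 (13). CXCL5 rose by 2.92 ± 0.33, CXCL10 by 3.16 ± 0.48, IER3 by 2.49 ± 0.25 and NR4A3 by 2.28 ± 0.24, CXCL10 only with the block (adjusted p = 0.053 without it). The 4 lists passed with an estimated correlation (largest adjusted p = 0.00173). Of 22 matrix proteases and inhibitors 9 rose and 1 fell (10 and 1 over the list alone), with adjusted p = 0.0033 at an estimated correlation with the block and 0.131 without it. MMP1 rose by 3.09 ± 0.40, MMP3 by 2.34 ± 0.38, PLAU by 2.21 ± 0.16 and ADAMTS4 by 1.83 ± 0.27. MMP3 and ADAMTS4 passed only with the block. Of 14 cell death regulators 2 rose (4 over the list alone), FAS by 1.91 ± 0.28 and MCL1, which opposes apoptosis, by 0.43 ± 0.13, MCL1 only with the block, and 5 rose after centring or a second quantile normalization. That list's adjusted p with an estimated correlation was 0.0464 with the block and 0.0523 without it.

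Of 16 prostaglandin genes 2 rose and 2 fell at 24 h, with PTGS2 and PLA2G2A (0.48 ± 0.14) higher, and PTGS1 lower by 0.82 ± 0.22 and HPGD, which inactivates prostaglandins, by 0.79 ± 0.22. Of these 4 only PTGS2 passed without the block. The progesterone receptor gene PGR fell by 1.12 ± 0.27 and HSD17B1, an estradiol-forming enzyme gene, by 0.94 ± 0.21, among 15 parturition-associated genes (1 rose and 3 fell, and 2 and 2 after centring). The estrogen receptor gene ESR1 rose by 0.84 ± 0.28 and STS, a steroid sulfatase gene, fell by 0.65 ± 0.18, both only with the block, and STS missed the threshold after centring (adjusted p = 0.051). MT2A and MT1X, metal-binding metallothionein genes, rose by 1.63 ± 0.20 and 1.08 ± 0.22, and they were the 2 of 7 list members past the test (adjusted p = 0.135 for the list with an estimated correlation). Of 9 NRF2 antioxidant genes 4 rose (over the list alone 5 rose and 1 fell), among them HMOX1 (1.06 ± 0.34) and TXN (0.48 ± 0.10), and only TXN passed without the block. That list's adjusted p was 0.302 with an estimated correlation. Of 14 genes of the unfolded protein and amino acid stress response 3 rose, PPP1R15A by 1.29 ± 0.15, CHAC1 by 1.28 ± 0.23 and DDIT4 by 0.96 ± 0.23, DDIT4 only with the block. Of 18 hypoxia genes 3 rose and 1 fell (4 and 0 after centring, and 4 and 1 after a second quantile normalization). ANGPTL4 was higher by 1.83 ± 0.30 and ADM by 0.70 ± 0.15, ADM only with the block. ANGPTL4 codes for an inhibitor of lipoprotein lipase. Of 23 interferon-stimulated genes 3 rose and 3 fell, and 4 and 3 after centring. GBP4 and GBP1 rose by 1.41 ± 0.42 and 1.29 ± 0.32 and OAS1 fell by 1.03 ± 0.20, and of these 3 only OAS1 passed without the block.

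Junction, matrix and receptor genes changed in both directions at 24 h. CLDN1 rose by 1.35 ± 0.28 and CLDN4 fell by 1.58 ± 0.34 among 13 epithelial junction genes (1 rose and 3 fell), CLDN4 with the block only (adjusted p = 0.051 without it). LAMB3 rose by 1.25 ± 0.15 and COL1A2, a collagen I chain, fell by 0.91 ± 0.21 with the block only, among 16 matrix structural genes (1 rose and 2 fell, but 3 and 1 after centring). TLR2 rose by 2.00 ± 0.19 and IRAK3, an inhibitor of Toll-like receptor signalling, by 0.92 ± 0.18, while NOD1 fell by 0.99 ± 0.28, among 19 pattern recognition genes (3 rose and 1 fell, and over the list alone 3 and 5). LYZ, the lysozyme gene, fell by 1.15 ± 0.25 with the block only, among 13 antimicrobial genes (1 rose and 1 fell). Of 9 cholesterol synthesis genes SQLE rose by 0.90 ± 0.28 and LSS fell by 0.74 ± 0.15, both with the block only. None of 6 heat shock genes passed, with a difference of 0.38 ± 0.14 for DNAJA1 (adjusted p = 0.08), and after centring 1 rose. Of 7 glucocorticoid-responsive genes 2 fell, SGK1 by 0.60 ± 0.16 and TSC22D3 by 0.56 ± 0.15 (TSC22D3 only with the block), and after centring the arrays neither passed (adjusted p = 0.066 and 0.055).

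In all, 387 genes rose and 988 fell at 24 h, and with the replicate block 809 rose and 2010 fell. The split depended on the scaling. The medians of the GBS arrays over the tested genes were 0.114 log2 below those of controls at 24 h, and after centring the arrays 622 genes rose and 553 fell, or 1345 and 1321 with the block. A second quantile normalization gave 518 and 554, or 1100 and 1325 with the block. Of the 179 named values past the blocked test, 163 passed under both scalings as well and none changed sign. The share of genes above the expression floor was 86.7 ± 0.7% in the GBS arrays (SD, n = 4) and 83.5 ± 0.8% in controls at that time. Without replicate number 1, 2 or 4 the unblocked count of 1375 was 429, 436 and 492, and the blocked count of 2819 was 1632, 1354 and 1341. Without GBS array 1, control array 2 or control array 4 of that time the unblocked count was 895, 912 and 864.

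**Figure D2:**
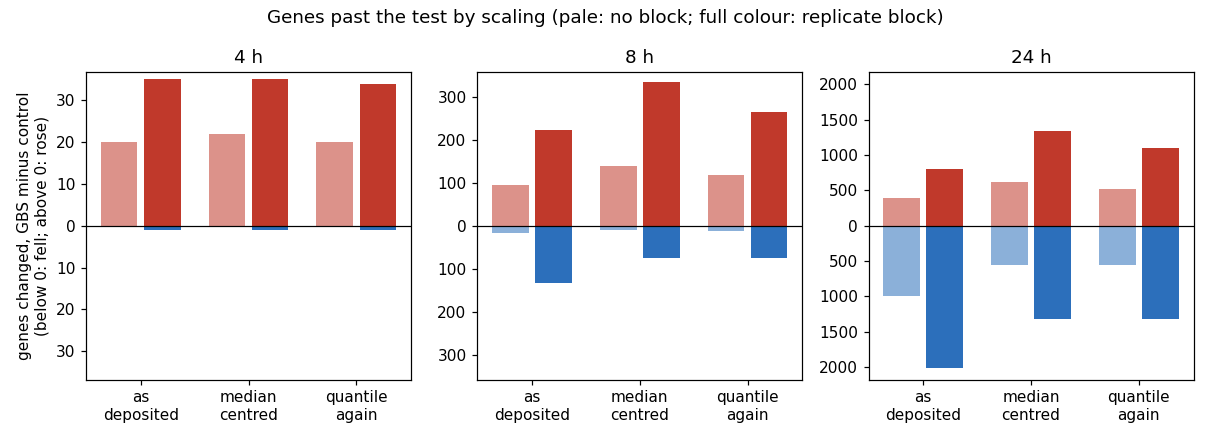
Numbers of genes past the test (vertical axis) that rose (red, above 0) or fell (blue, below 0) with GBS at 4, 8 and 24 h, for the values as deposited, centred on each array's median and quantile normalized again. Pale bars are from the fit without the replicate block and full colours from the fit with it. At 24 h 988 genes fell and 387 rose as deposited, and 553 fell and 622 rose after centring.

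Markers of cell types were compared as RNA levels, which do not measure the cell composition of the punches. Of 10 macrophage markers 4 fell at 24 h, MRC1 by 2.33 ± 0.34, LYVE1 by 1.45 ± 0.39, CD163 by 1.08 ± 0.29 and C1QC by 0.59 ± 0.18. MRC1 alone passed without the block, and CD163 and C1QC missed the threshold after a second quantile normalization (adjusted p = 0.055 and 0.14). CD68, the marker with the highest level, was 11.03 ± 0.40 in controls and 10.90 ± 0.38 with GBS. The macrophage list's adjusted p was 0.473 at 24 h with an estimated correlation. DKK1 fell by 2.61 ± 0.29 among 7 decidual stroma markers (2 fell, and 1 after centring) and PDGFRB by 0.94 ± 0.17 among 6 fibroblast markers, PDGFRB with the block only. SFN rose by 1.89 ± 0.24 among 6 epithelial markers (1 rose, and 2 after centring, adjusted p = 0.302 for the list with an estimated correlation) and IL7R by 1.35 ± 0.21 among 6 T cell markers. Of 6 endothelium markers CDH5 was higher by 1.19 ± 0.30, TEK lower by 1.04 ± 0.32 and EMCN lower by 0.56 ± 0.17, all with the block only, and after centring only CDH5 passed. GNLY rose by 0.66 ± 0.20 among 6 NK cell markers with the block only. Of 11 trophoblast markers PAGE4 was lower by 0.62 ± 0.18 (adjusted p = 0.023), not in all pairs, and it missed the threshold without the block, while after centring 1 of the 11 rose and 0 fell. No marker of neutrophils, B cells, smooth muscle or erythroid cells passed at any time as deposited, and after centring 1 of 5 erythroid markers rose at 24 h.

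**Figure D3:**
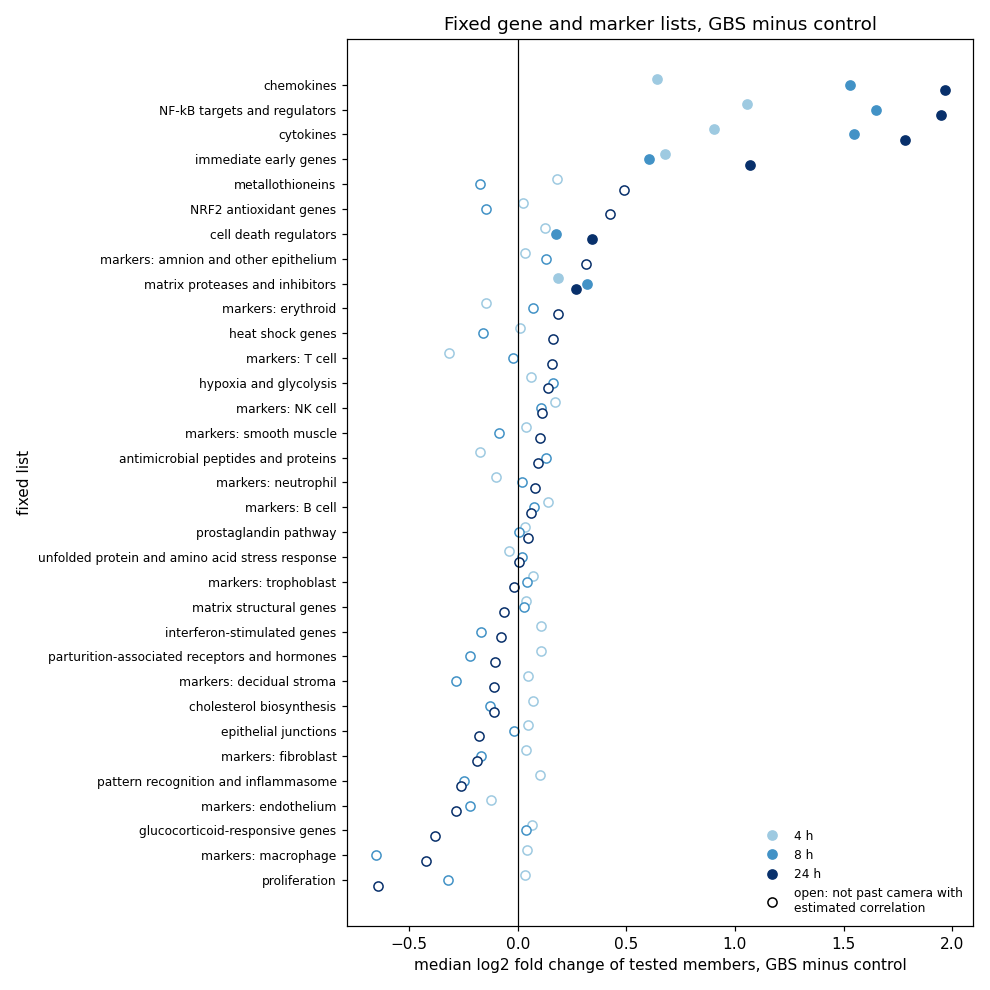
Median log2 fold change, GBS minus control, over the tested members of each of the 33 fixed lists (horizontal axis) at 4 h (pale), 8 h (medium) and 24 h (dark), 1 row per list. Filled points passed camera with an estimated correlation and the replicate block. The chemokine, NF-κB, cytokine and immediate early lists are filled at all 3 times, with medians of 1.97, 1.95, 1.78 and 1.07 at 24 h.

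Cell cycle genes differed at 24 h. Of 20 proliferation genes 12 fell with GBS (14 over the list alone), among them BUB1 by 2.22 ± 0.32, TOP2A by 2.03 ± 0.32, MKI67 by 1.97 ± 0.27 and CCNA2 by 1.89 ± 0.31. Without the block 7 of the 20 fell, and with the block 10 fell after centring and 7 after a second quantile normalization. The list's adjusted p was 0.135 with an estimated correlation and the block. In controls the same list moved the other way between 4 and 24 h, where 8 of 20 rose (13 over the list alone, adjusted p = 0.087 with an estimated correlation). Both contrasts use the same control arrays of 24 h with opposite sign, so they are not independent observations. MKI67, a marker of cycling cells, was 5.32 ± 0.47 in controls at 4 h, 7.21 ± 0.67 in controls at 24 h and 5.25 ± 0.41 with GBS at 24 h.

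The controls showed what time in culture did without GBS. From 4 to 24 h TOP2A rose by 2.32 ± 0.32, MKI67 by 1.89 ± 0.27, the linker histone gene H1-5 by 1.88 ± 0.25, HMMR by 1.84 ± 0.21 and SNORD114-2 by 2.48 ± 0.46, the last from 1.16 ± 0.31, close to the floor. The metallothionein gene MT1G fell by 2.14 ± 0.38, RRS1, a ribosome assembly gene, by 1.85 ± 0.27, OR5H14 by 1.96 ± 0.49, CHML by 1.69 ± 0.17 and HUNK by 1.57 ± 0.35. Of these 10 genes SNORD114-2, MKI67, H1-5 and HMMR passed without the block as well. In all 11 genes rose and 39 fell, and with the replicate block 145 rose and 321 fell. Leaving out any of the 8 control arrays gave 6 to 137 genes, and leaving out a replicate number 0 to 26. Without number 1, 2, 3 or 4 the blocked count of 466 was 65, 160, 51 and 151. Between 4 and 8 h 0 genes passed in either fit, with 504 at an unadjusted limma p under 0.05 without the block and 850 with it.

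The interaction contrast asked whether the GBS effect differed between times. From 4 to 24 h the effect grew by 3.56 ± 0.87 for CSF3, 3.01 ± 0.52 for TNFAIP6, 3.01 ± 0.47 for PTGS2, 2.75 ± 0.46 for CXCL5 and 2.74 ± 0.30 for CCL5. For PTGS2 part of this was a fall in controls, whose arrays lay at 5.52 to 6.43 at 4 h and 3.78 to 5.56 at 24 h. With GBS they lay at 7.05 to 7.65 and 8.24 to 9.84. The difference was -4.13 ± 0.74 for MPEG1, -4.02 ± 0.81 for SNAR-E, -3.72 ± 0.91 for SNORD114-17, -3.62 ± 0.65 for SNORD114-2 (with controls at 4 h close to the expression floor) and -3.23 ± 0.56 for FPR3. Adjusted p-values were at most 0.036 with the block, and PTGS2, CCL5 and SNORD114-2 passed without it. CSF3 missed the threshold after a second quantile normalization (adjusted p = 0.051). For TNF and SELE the differences of 0.25 ± 0.49 and 1.31 ± 0.67 did not pass (adjusted p = 0.849 and 0.343). In all 34 genes differed (12 up and 22 down), after centring 21 (13 up and 8 down) and after a second quantile normalization 30 (18 up and 12 down). With the replicate block 454 differed (87 up and 367 down). The blocked counts were 144 up and 189 down after centring, and 143 and 193 after a second quantile normalization. Leaving out any 1 of 9 of the 16 arrays gave 2 to 106 genes, and without replicate number 1, 2 or 4 the count was 1, 0 and 1. Without number 1, 2, 3 or 4 the blocked count of 454 was 69, 12, 311 and 52. Between 4 and 8 h 0 genes passed in either fit, with 791 at an unadjusted limma p under 0.05 without the block and 1364 with it.

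Averaged over the 3 times, 331 genes rose and 569 fell with GBS, with the replicate block 614 and 1484. After centring 444 rose and 242 fell (966 and 828 with the block), and after a second quantile normalization 382 and 301 (761 and 924 with the block). Without replicate number 1, 2 or 4 the total of 900 was 279, 272 and 320, and the blocked total of 2098 was 1002, 937 and 875. Of the 20 genes that rose at 4 h, 19 also rose at 8 h and 19 at 24 h, where independent lists would share 0.0972 and 0.400. Of the 94 that rose at 8 h 77 rose at 24 h (1.88 for independent lists), and of the 17 that fell 8 fell at 24 h (0.868). No gene was called in opposite directions at different times. Across genes, which are not independent replicates, the effects at 8 and 24 h correlated with Pearson r = 0.577 and Spearman rho = 0.460. The effects at 4 h correlated less with those at 8 h (r = 0.276, rho = 0.099) and at 24 h (r = 0.235, rho = 0.135). Each time has its own control arrays, but the replicate numbers pair the arrays across times.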

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

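The test of macrophage loss, the removal of the span trend and the comparison of array percentiles at 24 h were chosen after the result was seen. The other tests of scaling, gene span, marker lists, leukocytes and endothelium were set down before their results were seen.

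The effect of GBS differed between 4 and 24 h for 34 genes without the block. With the block 22 of 38 named genes differed, of which 10 were named for that difference. Of the 22 only PTGS2, COLEC12, ICAM1, IL6-AS1, CCL5 and SNORD114-2 passed without the block. The rise with GBS was larger at 24 h by 1.54 log2 for IL6, 3.01 for PTGS2, 3.56 for CSF3, 3.01 for TNFAIP6, 2.41 for ICAM1, 2.28 for IL6-AS1, 2.75 for CXCL5 and 2.74 for CCL5. For PTGS2 part of this was a fall in controls between 4 and 24 h. The difference was -2.65 for DKK1, -4.13 for MPEG1, -1.64 for ADAP2, -2.70 for FGL2, -2.27 for RNASE6, -2.04 for COLEC12 and -3.23 for FPR3. It was -3.72 for SNORD114-17, -3.62 for SNORD114-2 (with controls at 4 h close to the expression floor), -4.02 for SNAR-E, -2.92 for MIR181B2, -3.06 for ZNF276-AS1 and -2.33 for ZNF493. FAM182A had a difference of 1.49, which rests on a GBS level at 4 h under the expression floor. In 1 of 35 splits of the arrays by time, the real one, as many as 34 genes differed, and the highest other split gave 0. These splits need not part the replicate numbers, so they do not exclude chance for paired arrays. Only 8 of the 35 part all 4 numbers, too few for a share under 0.05, and the highest of the others among these gave 0. Without replicate number 1, 2 or 4 the count was 1, 0 and 1. Between 4 and 8 h the count was 0 and the highest other split gave 1, so all 35 splits reached it.

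More genes fell than rose at 24 h, and centring the arrays brought the share of falls from 71.9% to 47.1%, and a second quantile normalization to 51.7%, but both would also even out a real majority of falls. Over all probesets the 24 h medians were 1.58 to 1.64 in GBS arrays and 1.49 to 1.57 in controls. The 75th percentiles were 3.43 to 3.48 and 3.55 to 3.60. That argues against a uniform downward offset of the GBS arrays. Centring took the median change over tested genes from -0.024 to 0.090. A difference in the shape of the distributions cannot be told apart from a real majority of falls, and shorter RNA in the GBS arrays stays open too. Across protein-coding genes the 24 h change fell with gene span (Spearman rho = -0.290, against 0.030 for controls over time), and the median change was 0.107 in the 20% of genes with the shortest span and -0.190 in the 20% with the longest. Span is the length of the gene on the genome (medians 4.15 and 161 kb in these groups) and not of its RNA. The trend therefore cannot decide whether RNA was shorter. With the span trend and each array's overall level removed together, 406 genes rose and 608 fell. An excess of falls remained, but the trend was not removed apart from the level. Loss of a cell type cannot be told apart from no loss, since 0 of 12 marker lists shifted down at 24 h without the block and 1, macrophages, with it (adjusted p = 0.0325 with the preset and 0.473 with an estimated correlation), and the bound set beforehand did not allow for fits that differ.

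Cytokine and chemokine genes rose at all 3 times. More leukocytes in the GBS punches would raise their markers with them. At 8 h the highest median over 5 leukocyte marker lists was 0.106 (NK cells, SD of 6 members 0.15), against 1.55 for the cytokines. A larger share of leukocytes is therefore argued against as the whole cause at 8 h. The endothelium markers, set against the rise of SELE, had a median of -0.218 at 8 h (SD of 6 members 0.61), so more endothelium is argued against as the cause of a 6.48 log2 rise. Both readings hold only as far as GBS did not lower these markers per cell, which was not measured. A smaller contribution of leukocytes or endothelium and a response of resident cells stay open, and the latter was not tested.

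Of 10 macrophage markers 1 fell at 8 h (0 after a second quantile normalization) and 4 at 24 h with the block, and the list's adjusted p with an estimated correlation was 0.15 and 0.473. All 10 were lower at 8 h, from -1.21 (MRC1) to -0.12 (C1QA), with a median of -0.65. At 24 h they ran from -2.33 (MRC1) to 0.24 (FOLR2), with a median of -0.42. A loss of macrophages large enough for the falls of MRC1 and MPEG1 would lower all markers that macrophages alone express. At 24 h 7 of 10 markers lay above a change of -1 by over 2 standard errors, and MRC1, LYVE1 and CD163 did not. Among the 7 were CD14 (-0.49 ± 0.21), C1QB (-0.33 ± 0.22) and C1QC (-0.59 ± 0.18). C1QA, also among them, had a mean of 1.51, too close to the expression floor to show such a fall. The values argue against such a loss as the whole cause only if other cells do not express these markers. The macrophages that remain must also not have raised them per cell. Neither was measured. A smaller loss with a further fall of some transcripts may remain, and the shift of 0.114 log2 in the array medians covers little of a change of -2.33. Whether the bacteria act on these genes in macrophages was not tested.

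Spacing between arrays stood out in 3 of 71 groups of 4, where chance gives about 1 in 20. The ratio of the gap to the range was 0.920 for the array medians of controls at 8 h, 0.842 for the paired differences of FAM182A at 4 h and 0.970 for those of PTX3 at 8 h. Probesets left out of the named genes also changed. Of 1604 with several symbols 2 passed at 4 h, 7 at 8 h and 72 at 24 h, and with the block 2, 6 and 164. Of 17939 with no symbol 9 passed at 8 h and 150 at 24 h, and with the block 2 at 4 h, 14 at 8 h and 288 at 24 h.

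Other splits of the arrays tested the counts. For GBS at 4, 8 and 24 h the real split gave 20, 111 and 1375 genes, and the highest of the other 34 splits gave 1, 1 and 33. For the average over times it gave 900, and the highest of 99 others 18. For controls at 24 and 4 h it gave 50, and the highest other 2. In each of these 5 cases 1 split, the real one, gave as many. These splits need not part the pairs, so they do not exclude chance for paired arrays. Only 8 of 35 part all 4 pairs, too few for a share under 0.05, and the others of these gave at most 0, 1 and 1 genes at the 3 times and 1 for controls at 24 and 4 h. For the average over times, splits that part all pairs were not counted separately. For controls at 8 and 4 h the count was 0 and the highest other 1, so all 35 splits reached it. For the number of gene lists past camera with the preset correlation chance is not excluded either. The real split gave 5, 10 and 8 lists at 4, 8 and 24 h, the highest others 14, 14 and 12, and 20, 8 and 15 of 35 splits gave as many. Among the 8 splits that part all 4 pairs, the highest others gave 4, 10 and 8 lists.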

How the results depend on the processing

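The removal of the gene span trend was chosen after seeing the data, and the other alternatives before. No result past its test passed in the opposite direction under an alternative, while medians of some lists that did not pass changed sign with the scaling at all 3 times, and the balance of rises and falls turned. After centring it was 1345 to 1321 at 24 h and 966 to 828 on average with the block. Without the block it was 622 to 553 at 24 h, 444 to 242 on average and 13 to 8 for the 24 h interaction after centring, and after a second quantile normalization 382 to 301 on average and 18 to 12 for the interaction. The replicate block gave 36, 355 and 2819 genes at 4, 8 and 24 h, 2098 on average, 454 for the 24 h interaction and 466 for controls at 24 h. As a random block the number gave 36, 239, 2383, 1724, 204 and 292. The block changed no call of a count of 0, and it added 4 list calls. Fits of only the groups compared gave 51 at 8 h, 234 at 24 h, 18 for the interaction and 1 for controls. They have fewer arrays and use those groups' own spread, and which of these lowered the counts was not tested. Adjustment over the 3 times together gave 47, 170 and 782. A fold threshold of 1 log2 unit gave 555 at 24 h, 130 on average and 28 for controls. Array weights gave 33 at 4 h, 58 for the interaction and 136 for controls. For controls a trended robust variance gave 86 and the stricter filter 83. Centring gave 21 for the interaction. With the span trend and array level removed and with the block the counts were 36, 382 and 2326. Leaving out arrays or numbers gave 14 to 22, 54 to 129 and 429 to 1670 genes at the 3 times, 272 to 1132 on average, 0 to 1 and 0 to 106 for the interactions at 8 and 24 h and 0 to 137 for controls at 24 h. With the block and without a replicate number the counts were 22 to 26, 127 to 331, 1341 to 2611, 875 to 2029, 12 to 311 and 51 to 160. Lists past camera fell to 5 at 8 h and 4 at 24 h with an estimated correlation, and to 5 at 8 h with fry. Correlations of effects under the stricter filter were 0.317 (4 and 8 h), 0.275 (4 and 24 h) and 0.607 (8 and 24 h), and without a replicate number 0.205 to 0.266, 0.191 to 0.235 and 0.508 to 0.559. Apart from changes that the construction sets (arrays left out, fewer genes, a fold threshold), the cause was not tested. Over all alternatives 856 list results were the same, 10 passed newly and 25 were lost, and for named genes 6449 were the same, 239 passed newly and 354 were lost. Signal near the floor limits small changes of dim genes.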

Other observations

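The tests in this part were chosen after seeing the data. Genes of zinc finger proteins (symbols that start with ZNF and a number) had a lower median change with GBS at 24 h than other genes. Of 451 tested 85 fell and 4 rose with the block (18.8% fell), against 1842 of 15295 other protein-coding genes (12%). Their median change was -0.28 and that of the others -0.04. In 10000 random sets of other genes, matched on bins of gene span and of mean level, the medians lay between -0.14 and 0.02. After centring the medians were -0.17 and 0.07, and the matched sets lay between -0.02 and 0.13. Genes are not independent, so the sets describe these arrays and give no p-value.

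Classes of short RNA genes were described at 24 h without a test of the class. The median change was 0.58 over 15 snRNA genes (4 rose and 1 fell) 0.22 over 149 snoRNA genes (21 rose and 7 fell) and 0.09 over 556 miRNA genes (13 rose and 15 fell), against -0.05 over 15746 protein-coding genes. After centring the medians were 0.69, 0.34, 0.20 and 0.06. Over the 20% of protein-coding genes with the shortest span the median was 0.107. For the snoRNA genes SNORD114-17 and SNORD114-2 the effect of GBS was lower at 24 h than at 4 h, and SNORD114-2 rose in controls over that time. The same control arrays enter both values.

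In controls, between 4 and 24 h, 3 of 9 NRF2 antioxidant genes fell (6 over the list alone, median -0.66), as did 2 of 6 heat shock genes (4 over the list alone, median -0.37). Neither list passed with an estimated correlation (adjusted p = 0.087 for both). PTGS2 fell by 1.504 ± 0.332 in controls over the same time (adjusted p = 0.0199).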
